A study of Mus musculus with 6 samples.

How the data were processed

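Whole-lung RNA of 3 wild-type and 3 Itln1 knockout libraries was measured after treatment of both genotypes with HDM. Per the labels' protocols, polyadenylated RNA was selected from total RNA with poly-T beads before sequencing. The deposited count table holds raw whole-number counts per gene for 54532 genes with Ensembl IDs, and the submitters' processing notes name featureCounts, Subread and the mm10 build without versions. The aligner and the strand setting are not given in the sources used here. The deposited FPKM table was tested against the counts, and each value equals the count divided by the gene length and by 1 effective library size per library. Depth ran from 15286924 to 19245433 counts per library, and 25564 genes had no count in any library. Floors allow for 3 counts and cover counting error only.

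Knockout was compared with wild type from the counts in R 4.3.3 with edgeR 4.0.16, using filterByExpr, trimmed-mean (TMM) scaling and the quasi-likelihood F-test with Benjamini-Hochberg adjustment over 16500 tested genes. A gene was called at an adjusted p under 0.05. Log2 fold changes came from this fit with edgeR's default prior count, CPM values were computed from TMM-scaled library sizes, and the principal components used log2 CPM with a prior count of 2. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic. It therefore restates the test and is not a separate estimate of error. In all, 51 gene lists were tested with limma 3.58.1 by camera with a preset inter-gene correlation of 0.01, where at least 5 members were tested, which left out 2 lists. Beside it stand camera with a correlation estimated per list and fry, which tests whether a list's genes move, on balance, one way. The calls near Itln1 were tested with Fisher's exact test in a window of 10 Mb. Reactome sets of 10 to 300 tested genes came from fgsea 1.28.0.

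The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took Itln1, the 10 largest increases and 10 largest decreases among called protein-coding genes with a mean of at least 1 CPM and no overlap between groups, up to 3 called members per list and direction, or up to 2 where none was called, and a panel of 15 type 2 genes. The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, other filters on low counts, a block by replicate number, limma on log2 of FPKM plus 1 or 0.1, removal of hemoglobin, immunoglobulin and mitochondrial genes, other thresholds, and leaving out each library in turn. Removal of each library's trend with GC content was added after seeing the data, as were Reactome sets with an estimated correlation.

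The fits were tested on simulated data, 3 simulations of this comparison over 16500 genes with 200 changed genes each. In these, edgeR recovered 51.8% of genes changed 1.5-fold, 76.9% of those changed 2-fold and 94.4% of those changed 4-fold, and 8.28% of its calls were false. Nothing in the labels names a batch, a collection time or the sex of the mice.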

Results

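The series measured gene expression by RNA sequencing of whole lung from 2 kinds of mice, wild type and Itln1 knockout. All mice had received HDM, which per the labels' protocols induced an asthma model. By the same protocols, 20 µg of HDM in 50 µl was given into the trachea on days 1, 3 and 5, and 20 µg was given again from day 11 to day 14. There were 3 libraries per genotype and no library from mice without HDM, so the data compare genotypes under HDM and hold no untreated background. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples. Chi-square per degree of freedom between libraries of a group ran from 6.32 to 31.9, where counting error alone gives about 1. This argues against repeat sequencing of the same library as the whole source of the spread. It does not show that the animals were separate, and preparation of the samples may still add to the spread. The wild-type libraries held 15799644, 16746198 and 15286924 counts and the knockout libraries 16780998, 17128716 and 19245433. Of 54532 genes in the table, 16500 had enough counts to be tested.

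Itln1, the deleted gene, encodes the secreted lectin intelectin-1 and lies on chromosome 1 from 171518122 to 171535294 on the minus strand of the mm10 build (ENSMUSG00000038209). Its counts were 11, 114 and 77 in the wild-type libraries and 2, 19 and 0 in the knockout libraries. In CPM, counts scaled to a common library size, this was 4.07 ± 3.05 in wild type and 0.415 ± 0.616 in knockout (SD, n = 3 each), and the count of 0 allows up to 0.161 CPM in that library. The log2 fold change of knockout minus wild type was -3.30 ± 0.97 (SE) with an adjusted p of 0.0722 in edgeR's quasi-likelihood test, so the difference did not pass the threshold of 0.05. Knockout replicate 2, at 1.12 CPM, lay above wild-type replicate 1, at 0.691 CPM. Which part of the gene was deleted is not given in the sources used here, so the counts in knockout can include transcript left from the altered gene. Without knockout replicate 2 the log2 fold change was -5.98 (adjusted p = 0.0108), and without wild-type replicate 1 it was -3.79 (adjusted p = 0.0299).

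The comparison asks which lung genes differ between Itln1-deficient and wild-type mice in this asthma model. In knockout lung 11 of 19 plasma cell and immunoglobulin genes and 11 of 18 markers of monocytes and interstitial macrophages were higher, calls that both lists lost with an estimated correlation (adjusted p = 0.167 and adjusted p = 0.103). The matrix proteases Mmp13 and Mmp12 were higher as well, and the scavenger receptor Marco, the chemokines Ccl17, Cxcl3 and Cxcl5, and the transcription factor Zbtb16 were lower. Osteopontin, encoded by Spp1, was at 391 CPM in wild type and 2601 CPM in knockout, a log2 fold change of 2.73 ± 0.28 (adjusted p = 4.59e-04). Zbtb16 fell from 120 to 7.55 CPM, a log2 fold change of -3.99 ± 0.11 that had the smallest adjusted p of all genes (7.00e-08). The arginase gene Arg1 rose by 1.68 ± 0.21 on the log2 scale (adjusted p = 0.00130). In contrast, the type 2 cytokine genes Il4 and Il13 were at 3.27 and 1.17 CPM in wild type and 3.52 and 1.39 CPM in knockout and did not pass the test.

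By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 712 genes were higher and 450 lower in knockout at an adjusted p under 0.05, 7.04% of the genes tested. Of these, 366 differed by at least 2-fold, 234 higher and 132 lower. In 4617 of the tested genes (28.0%) the values of the 2 groups did not overlap, where chance gives 10%. The first principal component, with 47.1% of the variance, separated the genotypes, and the second, with 21.3%, set knockout replicate 2 apart from knockout replicate 3. Without trimmed-mean scaling, by library size alone, 564 genes were higher and 721 lower, so the share of higher genes among the calls was 43.9% in place of 61.3%. The counts dropped to 387 higher and 206 lower without wild-type replicate 2, to 301 and 144 without wild-type replicate 3, and to 456 and 255 without knockout replicate 1, and genes past 2-fold dropped to 240 and 228 without wild-type replicates 2 and 3 in turn.

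**Figure D1:**
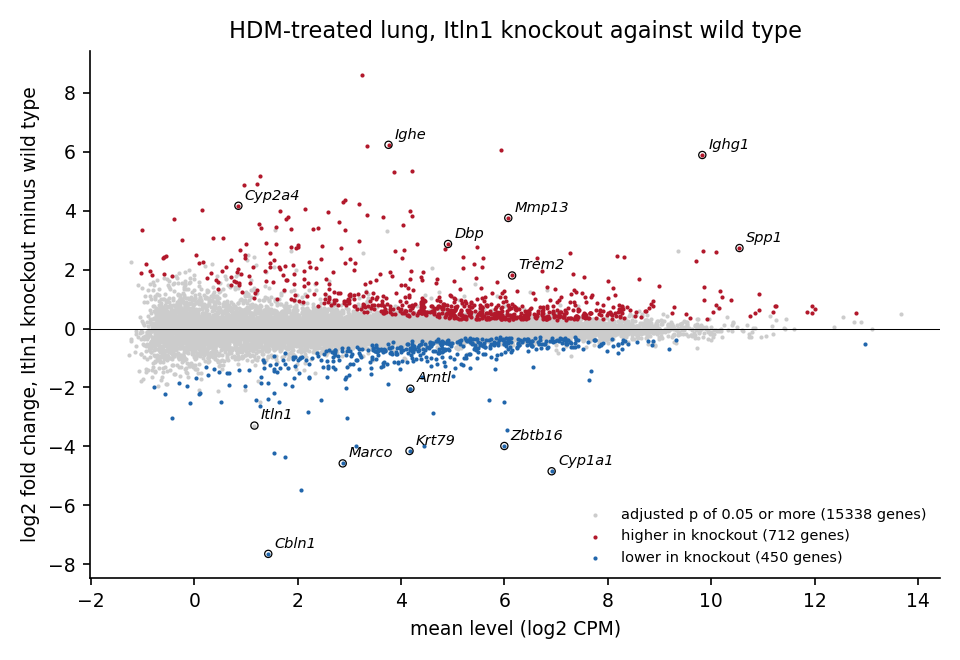
Log2 fold change of knockout minus wild type (vertical axis) against mean level in log2 CPM (horizontal axis) for the 16500 tested genes, 1 point per gene. Red points are the 712 genes higher and blue points the 450 genes lower in knockout at an adjusted p under 0.05, grey points are the rest, and circles mark named genes.

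Among protein-coding genes whose group values did not overlap, the 10 largest increases included Cyp2a4, a cytochrome P450, the neuropeptide gene Npy, Mmp13, and Duoxa1, the maturation factor of a hydrogen peroxide-producing oxidase of the airway lining. Mmp13, a collagenase, rose from 9.29 ± 4.39 to 126 ± 37.4 CPM (SD, n = 3 each), a log2 fold change of 3.75 ± 0.32. Npy was at 0.362 CPM in wild type and 5.91 CPM in knockout, and Duoxa1 at 0.125 and 2.11 CPM. The carbonic anhydrase gene Car3 and the complement factor D gene Cfd, both abundant in fat, were past the threshold with log2 fold changes of 3.61 and 3.36, but knockout replicate 2 held 29.6 and 30.9 CPM of them against at most 6.65 CPM in the other knockout libraries. When knockout replicate 2 was left out, both were still called. Both lost the call without wild-type replicate 1 (adjusted p = 0.0839 for Car3 and 0.104 for Cfd), without wild-type replicate 2 (0.0986 and 0.117) and without wild-type replicate 3 (0.119 and 0.107), as well as by limma-voom (0.150 and 0.146) and on log2 of FPKM plus 1 (0.153 and 0.110) or plus 0.1 (0.0882 and 0.0938). Of the largest decreases, Cyp1a1, the classical target of the aryl hydrocarbon receptor, fell from 233 to 8.04 CPM, a log2 fold change of -4.85 ± 0.46. The formyl peptide receptor genes Fpr1 and Fpr2 fell by 4.21 and 4.00 on the log2 scale, and Fbp1, a gluconeogenic enzyme, fell by 3.44. Cbln1, a cerebellin, was at 5.37 CPM in wild type and 0.0197 CPM in knockout, too few counts there for a fold.

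None of the 14 tested members of the list of type 2 cytokines and alarmins passed edgeR's test, over all genes or adjusted over the list alone, where 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The member called by DESeq2 was Crlf2, a subunit of the receptor for the alarmin TSLP, at 42.0 CPM in wild type and 60.7 CPM in knockout (adjusted p = 0.0915 by edgeR and 0.0217 by DESeq2). Crlf2 passed edgeR's test without wild-type replicate 2 (adjusted p = 0.0130) and with the GC trend removed, an alternative chosen after seeing the data (0.0466). It also passed with no filter on low counts (2.89e-05), a fit whose p-values are not a sound measure of the spread between libraries, as seen for Clca1 below. Its adjusted p reached 0.317 in other alternatives. Il33, an alarmin released by damaged epithelium, was at 647 CPM in wild type and 781 CPM in knockout (log2 fold change 0.27 ± 0.11, adjusted p = 0.184). Il5 and the eosinophil peroxidase gene Epx, with 34 and 16 counts in all 6 libraries, were too low to be tested. The chitinase-like gene Chil3 and the resistin-like gene Retnla, products of IL-4 and IL-13 signalling in the lung, had log2 fold changes of -0.01 ± 0.15 and 0.21 ± 0.14. In the list of mucous and IL-13 epithelial genes, 3 of 21 members were higher and 1 lower (3 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.567, and adjusted p = 0.869 with an estimated correlation). Without knockout replicate 3 it was called higher (adjusted p = 6.28e-04), and its adjusted p ran from that value to 0.990 over 18 alternatives. The mucin gene Muc5ac was at 35.9 ± 15.5 CPM in wild type and 33.6 ± 27.0 CPM in knockout. Clca1, a goblet cell product, was at 855 ± 48.4 CPM in wild type but at 1194, 2874 and 137 CPM in the knockout libraries (adjusted p = 0.617). Without knockout replicate 3 it passed the threshold with a log2 fold change of 1.25 (adjusted p = 0.0218), while without knockout replicate 2 its log2 fold change was -0.36. With no filter on low counts edgeR gave an adjusted p of 7.59e-09 at a log2 fold change of 0.70. That p-value cannot measure the spread between libraries, as the knockout values lay on both sides of wild type.

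**Figure D2:**
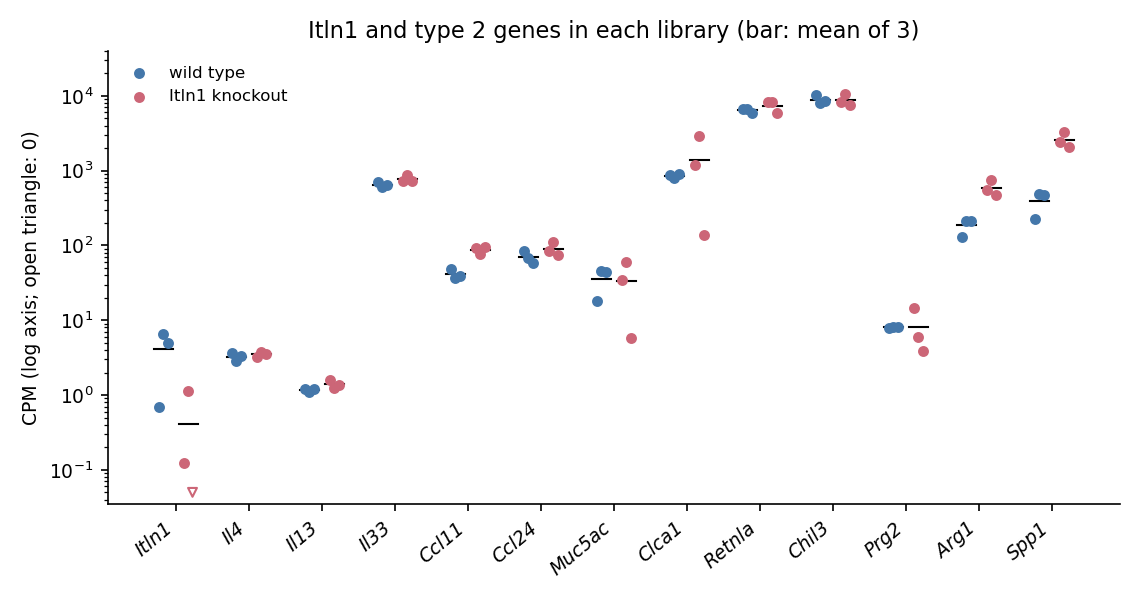
Level of Itln1 and of type 2 genes (horizontal axis) in each of the 6 libraries, in CPM on a log axis (vertical axis), with 1 point per library, wild type in blue, knockout in red, a bar at the mean of 3 libraries, and an open triangle for the 0 counts of Itln1 in knockout replicate 3. Ccl11, Arg1 and Spp1 were higher in every knockout library, and Clca1 ranged from 137 to 2874 CPM in knockout.

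Chemokine genes that draw eosinophils and monocytes were mostly higher in knockout. Of 11 tested members, 7 rose and 1 fell (7 and 2 adjusted over the list alone). The chemokine list had an adjusted p of 4.53e-07, and adjusted p = 0.167 with an estimated correlation. Ccl11, which encodes eotaxin, rose by 1.08 ± 0.12, Ccl8 by 1.37 ± 0.14 and Ccl9 by 1.46 ± 0.16 on the log2 scale, while Ccl17, a ligand of the Th2 receptor CCR4, fell by 2.51 ± 0.19. The eotaxin-2 gene Ccl24 was at 69.8 CPM in wild type and 89.3 CPM in knockout and did not pass (adjusted p = 0.217). Only with no filter on low counts did it pass (adjusted p = 0.0140), a fit whose p-values are not a sound measure of the spread between libraries. Of 10 tested eosinophil markers, 4 fell and 0 rose (4 and 0 adjusted over the list alone). The eosinophil list had an adjusted p of 7.50e-08, and adjusted p = 0.167 with an estimated correlation. Those that fell are also found on macrophages, namely the ribonuclease genes Ear1 (-4.36 ± 0.30) and Ear2 (-1.74 ± 0.18), whose near-identical family members can share reads, and the lectin genes Siglece (-1.32 ± 0.18) and Siglecf (-1.12 ± 0.26). The granule protein gene Prg2 was at 8.06 CPM in wild type and 8.14 CPM in knockout (adjusted p = 0.994). Siglecf lost its call without wild-type replicate 1, 2 or 3 (adjusted p = 0.106, 0.0865 and 0.110), and on log2 of FPKM plus 1 or 0.1 (0.0675 and 0.0794).

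Neutrophil genes were lower in knockout, with 6 of 14 tested members down and 1 up (8 and 1 adjusted over the list alone). The list had an adjusted p of 4.53e-07, and adjusted p = 0.167 with an estimated correlation. Cxcl5, an epithelial chemokine for neutrophils, fell by 2.06 ± 0.17, the gelatinase gene Mmp9 by 1.36 ± 0.20 and the chemokine receptor gene Cxcr2 by 1.22 ± 0.19 on the log2 scale. The member that rose was Lcn2, an iron-binding protein that epithelium makes as well (0.70 ± 0.09). In the list of classical macrophage activation and inflammasome genes, 4 of 20 members fell and 1 rose (4 and 3 adjusted over the list alone), among them Cxcl3 (-3.99 ± 0.44) and the interleukin-1 beta gene Il1b (-1.27 ± 0.21). This list had an adjusted p of 0.0160, and adjusted p = 0.480 with an estimated correlation, and lost its call without wild-type replicate 2 (adjusted p = 0.0860), by limma-voom (0.191) and on log2 of FPKM plus 1 or 0.1 (0.173 and 0.204).

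Immunoglobulin genes made up 0.712 ± 0.197% of the counts in knockout and 0.130 ± 0.0236% in wild type (SD, n = 3 each). Of 19 tested members of the plasma cell and immunoglobulin list, 11 rose and 0 fell (15 and 2 adjusted over the list alone), with a list adjusted p of 2.56e-21, and adjusted p = 0.167 with an estimated correlation. Ighg1, the constant region of IgG1, went from 30.0 ± 18.8 to 1788 ± 626 CPM, a log2 fold change of 5.89 ± 0.53, and Jchain, which joins IgA and IgM, rose by 2.41 ± 0.16. Ighe, the constant region of IgE, chosen after its values were seen, was at 0.340 ± 0.288 CPM in wild type and 26.7 ± 18.6 CPM in knockout (log2 fold change 6.24 ± 0.74, adjusted p = 9.64e-04). Of 135 tested immunoglobulin gene segments, whose similar sequences can share reads, 65 were higher and 2 lower. B cell surface markers went the other way, with 5 of 16 lower and 0 higher (9 and 1 adjusted over the list alone), among them Ighd, the constant region of IgD on naive B cells (-1.33 ± 0.17), and the IgM receptor gene Fcmr (-1.18 ± 0.20). The B cell list had an adjusted p of 2.04e-05, and adjusted p = 0.437 with an estimated correlation. Of 20 T cell markers 1 fell and 0 rose (1 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.617, and adjusted p = 0.877 with an estimated correlation). None of the 14 tested T cell receptor segments passed, 0 with an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

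Of 18 monocyte and interstitial macrophage markers, 11 rose and 1 fell (12 and 2 adjusted over the list alone), with a list adjusted p of 1.71e-19, and adjusted p = 0.103 with an estimated correlation. The lipid-sensing receptor gene Trem2 rose by 1.80 ± 0.13, the complement gene C1qc by 1.08 ± 0.08 and the lysosomal gene Cd68 by 1.07 ± 0.09 on the log2 scale. Of 18 alveolar macrophage markers, 8 fell and 3 rose (9 and 5 adjusted over the list alone), with a list adjusted p of 1.66e-04, and adjusted p = 0.256 with an estimated correlation. Among the members that fell, Ear1, Ear2 and Siglecf also belong to the eosinophil list, so the calls of these lists are not independent. The alveolar macrophage list was not called on log2 of FPKM plus 1 or 0.1 (adjusted p = 0.0669 and 0.0891). Marco fell from 14.1 to 0.585 CPM (-4.58 ± 0.38) and the keratin gene Krt79 from 33.9 to 1.93 CPM (-4.16 ± 0.43), while the proton pump gene Atp6v0d2 rose by 1.13 ± 0.12. Among 20 genes of alternative macrophage activation, 4 rose and 3 fell (5 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.528, and adjusted p = 0.869 with an estimated correlation). Without wild-type replicate 1 it was called higher (adjusted p = 0.0387), and its adjusted p ran from that value to 0.913 over 18 alternatives. Mmp12, an elastase of macrophages, rose by 1.42 ± 0.16, and the C-type lectin gene Cd209a fell by 1.65 ± 0.17. Hemoglobin genes, which mark red cells, moved with these groups, at 0.0722 ± 0.00875% of counts in knockout and 0.0242 ± 0.0135% in wild type.

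**Figure D3:**
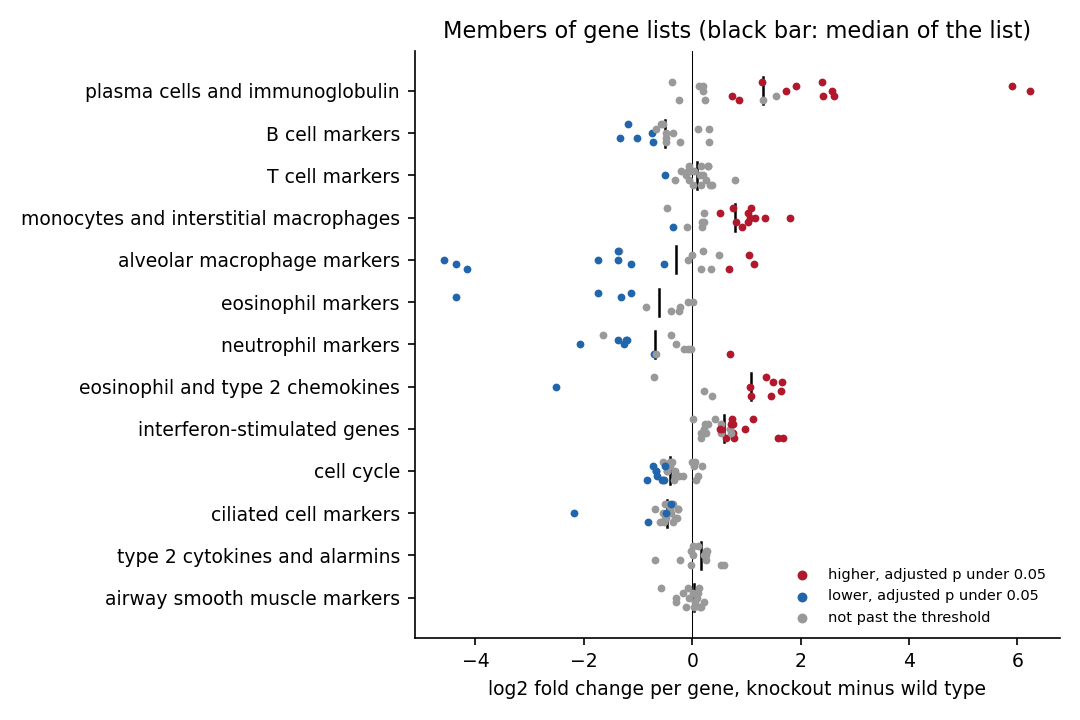
Log2 fold change of knockout minus wild type (horizontal axis) for each tested member of 13 gene lists (vertical axis), 1 point per gene, red where higher, blue where lower and grey where not past an adjusted p of 0.05, with a black bar at the median of the list. The median was 1.30 for plasma cell and immunoglobulin genes, -0.51 for B cell markers and 0.09 for T cell markers.

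Interferon-stimulated genes rose in 12 of 24 members with 0 lower (16 and 0 adjusted over the list alone). The interferon list had an adjusted p of 2.34e-18, and adjusted p = 0.167 with an estimated correlation. The antiviral transcription factor gene Irf7 rose by 1.58 ± 0.13 and Oas2, which encodes an enzyme activated by double-stranded RNA, by 1.68 ± 0.15 on the log2 scale. In the list for antigen presentation 4 of 18 members rose and 0 fell (4 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.0930, and adjusted p = 0.734 with an estimated correlation). It was called higher without wild-type replicate 2 (adjusted p = 0.0227), without knockout replicate 2 (0.00484), by DESeq2 (0.0131) and with no filter on low counts (0.0431), and its adjusted p reached 0.522 in other alternatives. The members that rose were of MHC class I or proteolysis, among them the cathepsin gene Ctss (0.98 ± 0.10) and H2-K1 (0.77 ± 0.10). Of 15 markers of group 2 innate lymphoid cells 3 rose and 0 fell (4 and 0 adjusted over the list alone), with a list adjusted p of 0.00120, and adjusted p = 0.167 with an estimated correlation. They were the growth factor gene Areg (1.99 ± 0.27), Il7r (0.94 ± 0.11) and Arg1, none of which is made only by these cells.

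The list of circadian clock genes had the highest share of changed members, with 11 of 16 higher and 3 lower in knockout (13 and 3 adjusted over the list alone), a list adjusted p of 1.09e-18, and adjusted p = 0.160 with an estimated correlation. Arntl and Npas2, activators of the clock, fell by 2.04 ± 0.12 and 2.02 ± 0.18 on the log2 scale. Dbp, an output factor of the clock, rose by 2.87 ± 0.17, and the repressor genes Per1, Per2 and Per3 rose by 1.21 ± 0.16, 1.70 ± 0.10 and 2.19 ± 0.12. Among 14 glucocorticoid-responsive genes 4 rose and 4 fell (6 and 5 adjusted over the list alone). The list was called lower (adjusted p = 0.00588, and adjusted p = 0.167 with an estimated correlation), with a mean log2 fold change of -0.26 but a median of 0.16. The glucocorticoid list was not called by limma-voom (adjusted p = 0.937) or on log2 of FPKM plus 1 or 0.1 (adjusted p = 0.852 and 0.882). Besides Zbtb16, the pyruvate dehydrogenase kinase gene Pdk4 (-1.54 ± 0.19) and the chaperone gene Fkbp5 (-0.61 ± 0.09) fell.

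**Figure D4:**
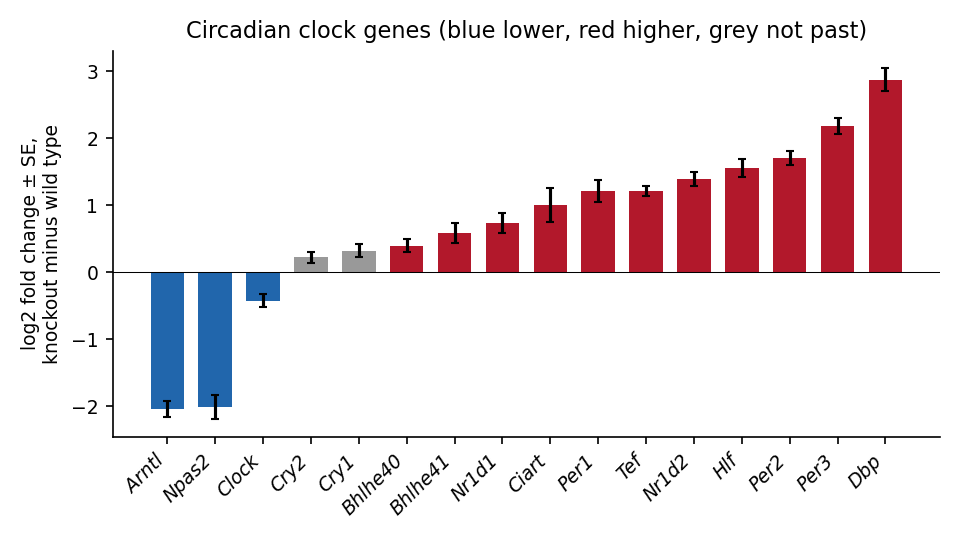
Log2 fold change ± SE of knockout minus wild type (vertical axis) for the 16 tested clock genes (horizontal axis), with blue bars lower, red bars higher and grey bars not past an adjusted p of 0.05. Of the 14 genes past the threshold, 3 were below 0 and 11 above 0.

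Among the cells of the lung wall, alveolar type 2 and surfactant genes were higher in 6 of 18 members with 0 lower (10 and 0 adjusted over the list alone). The alveolar type 2 list had an adjusted p of 3.65e-06, and adjusted p = 0.451 with an estimated correlation. Scd1, a lipid desaturase of surfactant synthesis, rose by 0.65 ± 0.11. Ciliated cell markers fell in 4 of 20 members with 0 higher (6 and 0 adjusted over the list alone), with a list adjusted p of 4.53e-07, and adjusted p = 0.402 with an estimated correlation. Mcidas, a regulator of multiciliated cells, fell by 2.19 ± 0.29. Endothelial markers fell in 4 of 20 members with 0 higher (7 and 1 adjusted over the list alone), with a list adjusted p of 1.30e-04, and adjusted p = 0.510 with an estimated correlation. Apln, a peptide of sprouting vessels, fell by 0.89 ± 0.13. Alveolar type 1 markers fell in 5 of 14 members and rose in 2 (6 and 3 adjusted over the list alone), led by Akap5 (-1.45 ± 0.10), with a list adjusted p of 0.0176, and adjusted p = 0.167 with an estimated correlation. The type 1 list lost its call without knockout replicate 1 (adjusted p = 0.0612), by limma-voom (0.0521) and on log2 of FPKM plus 1 or 0.1 (0.0635 and 0.0763). Cell cycle genes fell in 8 of 26 members with 0 higher (16 and 0 adjusted over the list alone). The cell cycle list had an adjusted p of 1.29e-06, and adjusted p = 0.477 with an estimated correlation. None of 16 airway smooth muscle genes passed, 0 with an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and of 24 collagen and matrix genes 2 rose, Mmp12 and the growth factor gene Ctgf (1.18 ± 0.14), adjusted over all genes or adjusted over the list alone. The collagen list did not pass (adjusted p = 0.145, and adjusted p = 0.825 with an estimated correlation), but was called higher without knockout replicate 2 (adjusted p = 1.55e-06) and by DESeq2 (0.0436), within a range up to 0.780 over 18 alternatives. The smooth muscle list was not called (adjusted p = 0.617, and adjusted p = 0.877 with an estimated correlation) except higher without knockout replicate 2 (adjusted p = 0.0116), within a range up to 0.959.

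In total, 12 of 49 tested lists were called higher and 14 lower by camera with a preset correlation of 0.01 between genes, and with an estimated correlation 0 were called, 14 of them having an unadjusted p under 0.05, while fry called 17. Among the 12 was the list of cardiac and pulmonary vein muscle, tissue that may be taken along with lung. None of its 14 tested members was called (list adjusted p = 0.0456), and the list lost its call in 7 of 18 alternatives. The preset correlation also called up to 17 lists when the 6 libraries were split in ways that mix the genotypes. Each part of such a split still held unequal numbers of the genotypes, so part of the genotype difference remained between the parts. The 17 lists are therefore no count of false calls. As 0 lists were called with an estimated correlation, the list p-values are to be read with caution beside the counts of changed members.

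Genes near Itln1 were examined because a deletion can bring DNA of another mouse strain along with it. Within 10 Mb of Itln1 on chromosome 1, 23 of 189 tested genes were called (12.2%), against 6.98% elsewhere, an odds ratio of 1.85 (95% confidence interval 1.13 to 2.88, two-sided Fisher's exact test p = 0.00944). Of 14 genes of the adjoining Slam receptor cluster, 3 rose and 0 fell (3 and 1 adjusted over the list alone). The Slam list had an adjusted p of 0.00588, and adjusted p = 0.167 with an estimated correlation. They were Slamf7 (chromosome 1 from 171632403 to 171653035, 0.78 ± 0.08), Cd84 (0.76 ± 0.09) and Ly9 (0.88 ± 0.11), receptors of lymphocytes and macrophages. Of the 23 called genes in the 10 Mb window 14 were higher and 9 lower. Among them, chosen after their values were seen, the interferon-inducible gene Ifi208 fell by 1.89 ± 0.17, while its relatives Ifi204, Ifi206 and Ifi207 rose by 0.92, 0.67 and 0.66.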

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

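The GC trend and the Reactome sets with an estimated correlation were chosen only after the results were seen. None of the 1162 calls changed its sign in any alternative that tested it. Genes lower in knockout were 721 with library size only, 681 by DESeq2, 946 with no filter on low counts, 237 and 215 on log2 of FPKM plus 1 and 0.1, and 795 and 138 at adjusted p under 0.1 and 0.01, against 450. Genes higher were 1162 with no filter, 468 on FPKM plus 0.1, and 1081 and 292 at those thresholds, against 712. Genes past 2-fold were 610 with no filter and 178 and 227 on FPKM plus 1 and 0.1, against 366. Lists called lower were 9 by limma-voom, 8 and 8 on FPKM plus 1 and 0.1, 6 by fry and 0 with an estimated correlation, against 14. Lists called higher were 0 with an estimated correlation, against 12, and Reactome sets were 0 in place of 35. By camera with that correlation, 14 of 49 lists but only 14 of 869 Reactome sets had an unadjusted p under 0.05. Leaving out 1 library gave 301 to 841 genes higher, 144 to 598 lower, 228 to 398 past 2-fold, 13 to 15 lists higher, 11 to 16 lists lower, and log2 fold changes of Itln1 from -5.98 to -2.68. Itln1, at -3.30 in both, had an edgeR adjusted p of 1.51e-15 with no filter and 0.0722 in the main fit, although its group values overlapped. The p-values with no filter are therefore not read as a measure of the spread between libraries. Itln1 also passed at -3.50 with a block by replicate number, although libraries of the same number did not resemble each other (correlations of -0.0241, 0.0109 and -0.0818). With that block 834 of the 1162 calls remained. The cause of these changes was not tested, except that the stricter and looser thresholds change counts by construction. Il5 and Epx, with 34 and 16 counts in all 6 libraries, were too low to be tested.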

Other observations

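The tests chosen only after the result was seen were those of collection time, glucocorticoid level and GC trend for the clock genes, those of lymphoid tissue, blood and GC trend for the immunoglobulin and macrophage genes, the share of called genes within 20 Mb of Itln1, the summed level of mt-Nd3 and its copy, and the Reactome sets with an estimated correlation. For the windows and the glucocorticoid targets, the rule that the exact 95% interval must clear the bound was set after the shares were seen.

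Members of further lists differed between the genotypes. Red cell genes rose in 8 of 12 tested members with 0 lower (8 and 0 adjusted over the list alone), among them the hemoglobin gene Hba-a1 (1.75, but adjusted p = 0.0646 without wild-type replicate 3 and 0.0507 on log2 of FPKM plus 0.1). The red cell list had an adjusted p of 1.43e-07, and adjusted p = 0.167 with an estimated correlation. Dendritic cell markers fell in 5 of 17 members and rose in 3 (6 and 3 adjusted over the list alone), led by Ccl17 and Cd209a, with an adjusted p of 0.00447, and adjusted p = 0.167 with an estimated correlation, and the list was not called by limma-voom (adjusted p = 0.0978) or on log2 of FPKM plus 1 or 0.1 (0.326 and 0.340). Complement and acute phase genes rose in 4 of 17 members with 0 lower (5 and 2 adjusted over the list alone), among them the anaphylatoxin receptor gene C3ar1, with an adjusted p of 0.0109, and adjusted p = 0.167 with an estimated correlation. Among 14 tested bone-associated factors 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Spp1 and the acid phosphatase gene Acp5 (0.69) higher and Mmp9 lower, and this list did not pass (adjusted p = 0.0664, and adjusted p = 0.265 with an estimated correlation). It was called higher in 5 of 18 alternatives, namely without wild-type replicate 1 (adjusted p = 0.0217), without knockout replicate 2 (0.0223), with a block by replicate number (0.0396), with a filter of 1 CPM in 3 libraries (0.0437) and without hemoglobin, immunoglobulin and mitochondrial genes (0.0483), and its adjusted p reached 0.198 in others. Among 20 genes of dissociation stress and immediate early response, a sign of sample handling, 4 rose and 0 fell (5 and 0 adjusted over the list alone), among them the heat shock genes Hspa1b (1.02) and Dnajb1 (0.52). This list did not pass (adjusted p = 0.0502, and adjusted p = 0.541 with an estimated correlation) but was called higher in 7 of 18 alternatives, among them without wild-type replicate 2 (adjusted p = 0.00452), without wild-type replicate 3 (0.0413) and without knockout replicate 1 (0.0417), and its adjusted p reached 0.775 in others. Of 869 Reactome sets 27 were called higher and 8 lower, among them trafficking of endosomal Toll-like receptors, with the cathepsin genes Ctsl, Ctsb and Ctss among 6 of 12 members higher (adjusted p = 2.54e-09, and adjusted p = 0.999 with an estimated correlation).

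The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The splits other than the real one keep part of the genotype difference between their parts and put part of it into the spread within them. Their counts are therefore no measure of false calls. The real split called 1162 genes, and the highest of the other splits 0, where 184 to 941 genes had an unadjusted p under 0.05 against 3652. Past 2-fold the counts were 366 and 0, and for lists 26 and 17, and for each of these 1 split of 10 gave a count as large. For Reactome sets the real split called 35 and the highest other 122, and 8 of 10 splits called as many. A count several times the real one points to a structure of the samples, or to the preset correlation calling too many sets. With an estimated correlation 0 of 869 sets were called in the real split, and 14 had an unadjusted p under 0.05. Whether the structure or the preset correlation was the cause was not tested.

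The clock genes moved in opposite phases. A GC trend between libraries is argued against as the whole cause, since 100% of the 14 called clock genes stayed past the threshold with the trend removed. A higher glucocorticoid level in knockout cannot be told apart from other explanations, as 42.9% of 7 called targets other than Per1 were higher (95% interval 9.90 to 81.6%), with Fkbp5, Zbtb16 and Pdk4 among those lower. A different time of day at collection may explain the pattern and stays open, as 100% of the called clock genes moved as their phase says. An effect of genotype on the clock was not tested and stays open as well.

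Called genes were more frequent near Itln1, and single genes elsewhere, among them mt-Nd3, differed strongly between the genotypes. Within 20 Mb of Itln1 lay 3.27% of the called genes, so most calls were at genes outside that stretch. This share cannot decide whether DNA of another strain beside Itln1 was their source. The window held only 303 of 16500 tested genes, so the share had to be low, and effects of such DNA on genes elsewhere were not tested. Ordinary clustering of calls along chromosomes cannot be told apart from an effect of the locus, as 4.8% of 125 other windows (6 windows, 95% interval 1.78 to 10.2%) had as high a share of called genes. The mitochondrial gene mt-Nd3 (-3.05) and its nuclear copy Gm28438 (2.73), the latter chosen after its values were seen, share 342 aligned bases with 0 differences. Their summed level differed by -0.16 on the log2 scale, so a move of reads between them may explain both. The move followed genotype in every library, with 25, 37 and 30 counts of Gm28438 in wild type and 174, 276 and 197 in knockout. Why reads would move with genotype was not tested, and a difference between the mice in these sequences stays open. Also chosen after their values were seen, Gm42031 was at 0.0403 CPM in wild type and at 18.9 to 19.1 CPM in the knockout libraries, Gm15446 was at 8.23 and 0.181 CPM, and Wdfy1 differed by a log2 fold change of 2.10, with the cause not tested.

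In the immunoglobulin and the monocyte lists 11 of 19 and 11 of 18 members were higher, while 8 of 18 alveolar macrophage markers were lower and 3 higher, and all 3 lists lost their call with an estimated correlation (adjusted p = 0.167, adjusted p = 0.103 and adjusted p = 0.256), the alveolar list also on log2 of FPKM plus 1 or 0.1 (0.0669 and 0.0891). Lymphoid tissue taken along with knockout lung was not seen as a rise of lymphocyte markers. The median log2 fold change was -0.51 for the B cell list and 0.09 for the T cell list. These lists cannot exclude such tissue, since they also count lymphocytes of the HDM-treated lung itself. More blood left in knockout lung stays open as a source of these groups. Red cell genes were higher in 8 of 12 members with 0 lower, while the median of the neutrophil list was -0.68. That list cannot decide the question, since in HDM-treated lung it also counts neutrophils in the tissue and genes that epithelium makes. A GC trend is argued against as the whole cause, since 97.1% of the 34 called members stayed past the threshold with it removed. An effect of genotype on the cells of the lung, or a difference between the mice apart from Itln1, was not tested and stays open.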
